A study of Drosophila melanogaster with 3 samples.

How the data were processed

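Small RNAs of Drosophila melanogaster ovaries were sequenced in 3 libraries, 1 per genotype. Per the labels, the flies were 3 to 5 days old and grown at 25 degrees. The WT rescue and DD rescue libraries came from an ago3 background carrying a Flag-tagged ago3 transgene, labelled WT or DD. Their genotype labels read nosP>flag-ago3WT;ago3 and nosP>flag-ago3DD;ago3. The ago3 mutant library carried no transgene in its label, which reads ago3 alone. The nosP element is therefore in both rescue labels and absent from that of the ago3 mutant. What DD stands for is not given in the sources used here. The series title says that the study concerned the Slicer activity of AGO3, the activity by which a PIWI-family Argonaute protein cuts its target RNA.

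Per the labels' protocols, total RNA was extracted with Trizol and depleted of 2S rRNA. RNAs of 15 to 35 nt were cut from a gel and cloned with the Ion Total RNA-Seq Kit. Ion sequencers, for which that kit is made, are prone to insertions and deletions in runs of a repeated base, which can lower the number of exact matches. The deposited files list each distinct sequence with its whole-number read count, and hold sequences of 19 to 29 nt. The counts are raw as deposited, with no normalization found in their values. Bowtie 0.12.7 is named in the submitters' processing notes without its role; the genome build, the length filter and any read filter are not given in the sources used here. One file held 1 blank line, which was skipped.

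The depth was 1478788 reads in WT rescue, 602488 in the ago3 mutant and 1279465 in DD rescue. Main values were scaled to these deposited totals as RPM, the usual scaled read count. Shares carry exact Clopper-Pearson intervals, rates exact Poisson intervals and ratios exact conditional Poisson intervals, all at 95%. Medians over regions carry order-statistic intervals. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. A region at 0 reads was set against a floor of 3 reads per library, which equals 2.03, 4.98 and 2.34 RPM in the WT rescue, ago3 mutant and DD rescue libraries. With 1 library per group no test between genotypes was possible, and no difference has a replicate check.

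No genome or transposon sequence was used here, and the files carry neither coordinates nor names. The planned comparisons by transposon family, by lists of families and by source loci such as flamenco were therefore replaced. The following replacement was designed after the data were seen. Reads of 23 to 29 nt, the usual piRNA length, were assembled into regions from words of 19 nt seen in at least 3 reads, extending to the most abundant unused neighbour. The pool held the reads of all 3 libraries. Regions of at least 60 nt were kept, a length set after other settings had been tried. This gave 1668 regions of 164487 bases in all, the longest of 851 nt. Reads were placed by exact match. Of the eligible reads, 50.1% were placed in WT rescue, 49.8% in the ago3 mutant and 51.0% in DD rescue. The assembly uses each word only once, which fixes at 0 the sequences with several places. This does not show that a sequence comes from a single copy in the genome. Regions are numbered by abundance and carry no coordinates, because no build was used. Regions that share an element are not independent of each other.

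Regions were classed without use of any ratio between libraries. A dual-strand region had at least 20% of its reads on the minor strand. A uni-strand region had at most 5% there, and was called U-rich when at least 40% of its distinct sequences began with U and U-poor below 30%. Dual-strand regions of at least 240 nt were oriented when a reading frame ran open from end to end on 1 strand and none did on the other; the strand with the frame was called sense.

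Other RNAs were recognised from sequences entered from general knowledge, not from an annotation. They comprised 31 microRNA arms, 14 of them fixed before the data were examined, with 5 tRNA 5′ ends, 5S and 2S rRNA and a 3′ part of 28S rRNA. A microRNA read had to share the first 18 nt of its arm and measure 19 to 25 nt. These reads were left out of the assembly. Annotated microRNA identifiers, snRNAs, snoRNAs, the traffic jam gene and the mus308 target were not analysed here.

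The ping-pong signal was taken from 5′ ends on opposite strands that overlapped by 1 to 20 nt. Pairs were weighted by the product of their counts, and the score at 10 nt was set against the other lengths as a z-score. The share of reads with a partner at 10 nt was computed as well. Both were repeated after thinning every library to equal reads in 10 draws. The likeness of both comparisons with WT rescue was computed with 0.5 added to each count, and set beside 1000 simulated unchanged pairs sharing that library. It was first computed over regions with enough reads in every library; the mean over the libraries was used after that result was seen, and both are given.

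For each comparison the rule for named items, fixed before the data were examined for transposon families, was applied to regions with at least 100 reads in 1 of the libraries compared. It takes the 10 lowest and 10 highest log2 ratios of at least 1 in size whose interval excludes 0, and the 5 most abundant regions of WT rescue. For microRNAs it takes the listed arms with at least 100 reads in any library. In tests on simulated data 100 of 100 simulated regions were assembled without error. These were unrelated random sequences with error-free reads. Related sequences and insertions or deletions were not simulated, so their effect on the assembly was not tested. Of counts simulated for 920 regions of the ago3 mutant against WT rescue, 96.0% of 2-fold and 100% of 4-fold differences had an interval excluding 0, as did 4.44% of unchanged regions. The values were 98.0%, 100% and 3.97% for 930 regions of DD rescue against WT rescue, and 99.0%, 100% and 2.86% for 375 regions of DD rescue against the ago3 mutant. These rates describe the interval alone. Counts of regions at least 2-fold lower or higher also required a log2 ratio of at least 1 in size, which was not simulated. The simulated counts follow the Poisson model of the interval, so the rates for unchanged regions were set by that model.

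Alternatives fixed before the data were examined were other normalizations, distinct sequences, 24 to 27 nt, other read minimums, 1 mismatch, uniquely placed reads, thinning and leaving out the 100 most abundant sequences. Others were added after seeing the data. They include scaling to a reduced piRNA total: reads of 23 to 29 nt without any recognised RNA, microRNAs included, and without all reads placed in uni-strand U-poor regions. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.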

Results

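Small RNAs were counted in 3 ovary libraries that differ in the state of ago3. AGO3 is a PIWI protein that takes part in the ping-pong cycle, in which sense and antisense piRNAs are made from each other by cleavage of their precursors. The comparisons ask how the piRNAs of ovaries without a rescuing transgene, and of ovaries carrying the DD transgene, differ from those carrying the WT transgene. Small RNA libraries do not check the ago3 genotype itself. The WT rescue library held 1478788 reads of 512525 distinct sequences, the ago3 mutant library 602488 reads of 144284 and the DD rescue library 1279465 reads of 315659. No group had a second library.

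Reads of piRNA length made up most of each library. The share of 23 to 29 nt was 78.6% in WT rescue (95% interval 78.5 to 78.6), 75.7% in the ago3 mutant (75.6 to 75.8) and 76.6% in DD rescue (76.5 to 76.7). This share includes fragments of other RNAs. Without the recognised RNAs it was 70.5%, 54.8% and 50.4% of each library in the same order. Of these remaining reads, 6.93%, 17.7% and 24.8% lay in uni-strand U-poor regions, which include rRNA. The most frequent length was 25 nt by reads and 26 nt by distinct sequences in each of the 3 libraries. Reads of 21 nt, the length of siRNAs, made up 6.75%, 7.14% and 7.17% in the same order.

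**Figure D1:**
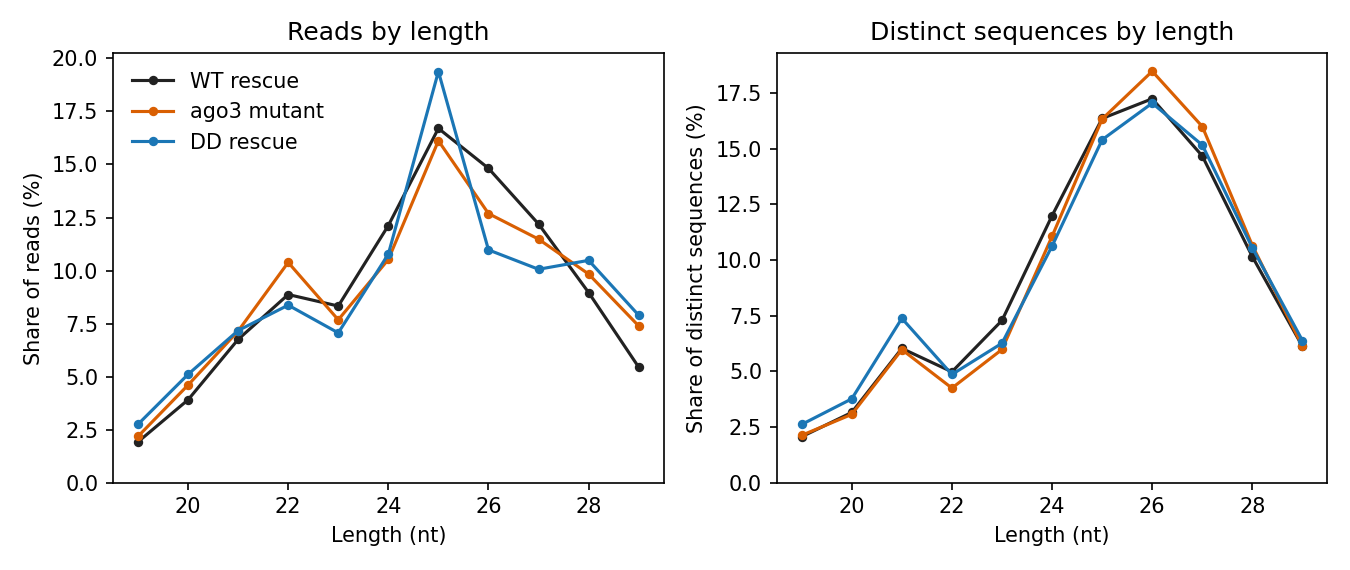
Share of reads (left) and of distinct sequences (right) in percent against length in nt, 1 line per library. By reads the DD rescue line peaks at 19.4% at 25 nt, where WT rescue has 16.7% and the ago3 mutant 16.1%; by distinct sequences the peaks at 26 nt are 17.04%, 17.2% and 18.5%.

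Fragments of structural RNA took a larger part of the ago3 mutant and DD rescue libraries. Recognised rRNA and tRNA fragments were 7.70% of reads in WT rescue (7.65 to 7.74), 20.8% in the ago3 mutant (20.7 to 20.9) and 26.6% in DD rescue (26.5 to 26.7). The 3′ part of 28S rRNA gave 16104 RPM (reads scaled to the library total) in WT rescue, 61600 in the ago3 mutant and 142705 in DD rescue. Fragments of 5S rRNA gave 20026, 66056 and 44567. The 5′ ends of tRNA-Asp gave 20950, 47706 and 48992, and those of tRNA-Glu-TTC 11598, 14417 and 11265. Because all values are shares of a library, these reads lower the share left to every other class.

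The recognised microRNAs summed to 70532 RPM in WT rescue (70105 to 70961), 100362 in the ago3 mutant (99564 to 101165) and 67426 in DD rescue (66977 to 67877). Of 30 arms with enough reads, 4 were at least 2-fold higher in the ago3 mutant than in WT rescue and 0 at least 2-fold lower, with a median log2 ratio of 0.55. These 4 were mir-996 at 1.33, mir-14 at 1.16, bantam, a growth-promoting microRNA, at 1.16 and mir-305 at 1.13. In DD rescue against WT rescue the median was 0.07; mir-92b at -1.32 and mir-92a at -1.02 were at least 2-fold lower and mir-996 at 1.06 was higher. Of the arms abundant in WT rescue, mir-318 was at 0.15 in the ago3 mutant and 0.02 in DD rescue, and mir-275 at -0.087 and -0.95. The follicle cell microRNA mir-989 was at 0.59 (0.41 to 0.77) and -0.31 (-0.48 to -0.13). Scaled to the summed microRNAs, every ago3 mutant ratio shifts by -0.51, which takes mir-318 below 0; the median was then 0.037, with 0 arms at least 2-fold higher and 1 lower. Scaled to the reduced piRNA total (piRNA-length reads outside all recognised RNAs and uni-strand U-poor regions), 17 arms were higher in the ago3 mutant and 0 lower. The same scaling shifts every DD rescue ratio by 0.79, which takes mir-989 above 0, with 11 arms higher and 0 lower. Scaled to microRNAs or to all piRNA-length reads, 1 arm was higher and 1 lower in DD rescue. The siRNA TTGACTCCAACAAGTTCGCTCC, recalled as a product of a hairpin transcript, gave 384 RPM in WT rescue (353 to 417), 880 in the ago3 mutant (806 to 958) and 411 in DD rescue (377 to 448).

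Reads starting with U, a mark of primary and antisense piRNAs, were most frequent in WT rescue. They made up 46.1% of 23 to 29 nt reads there (46.0 to 46.2), 38.9% in the ago3 mutant (38.8 to 39.1) and 28.7% in DD rescue (28.6 to 28.8). Adenine at position 10, a mark of secondary piRNAs, was present in 31.9% (31.8 to 32.0), 25.1% (25.0 to 25.3) and 20.6% (20.5 to 20.7). Within dual-strand regions the first-base U shares were 46.4%, 41.9% and 38.2%, while adenine at position 10 was present in 37.5%, 39.6% and 33.0%. There the ago3 mutant was above WT rescue, with intervals of 39.3 to 39.97 and 37.3 to 37.6. Among reads of these regions that did not start with U, the order was the other way. Adenine at position 10 was then present in 44.5% in WT rescue (44.3 to 44.8), 43.1% in the ago3 mutant (42.6 to 43.5) and 34.9% in DD rescue. Counted by distinct sequence, first-base U was 44.6%, 43.9% and 38.6%.

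A 10-nt overlap of opposite-strand 5′ ends stood out in WT rescue and the ago3 mutant and was small in DD rescue. It held 35.5% of weighted pairs in WT rescue (31.0 to 40.1 by resampling regions), 34.1% in the ago3 mutant (26.8 to 39.7) and 8.71% in DD rescue (7.37 to 10.1). The mean of the other lengths was 3.39%, 3.47% and 4.80%, and the z-scores were 34.8, 30.4 and 4.07. The ago3 mutant differed from WT rescue in another measure: 41.1% of placed reads had a 10-nt partner in WT rescue (40.9 to 41.2), 16.5% in the ago3 mutant (16.3 to 16.7) and 15.1% in DD rescue (15.0 to 15.2). With all libraries thinned to 602488 reads these shares were 33.7%, 16.5% and 11.3%. Within dual-strand regions at 72989 placed reads each, they came to 38.7%, 35.7% and 33.6%, but the excess over the other lengths was 21.95, 20.1 and 5.88 percentage points. Recognised rRNA and tRNA fragments, which were left out of the assembly, made up 7.70%, 20.8% and 26.6% of all reads in the same order. Uni-strand U-poor regions, which include rRNA, held a further 48860, 96986 and 124944 RPM.

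**Figure D2:**
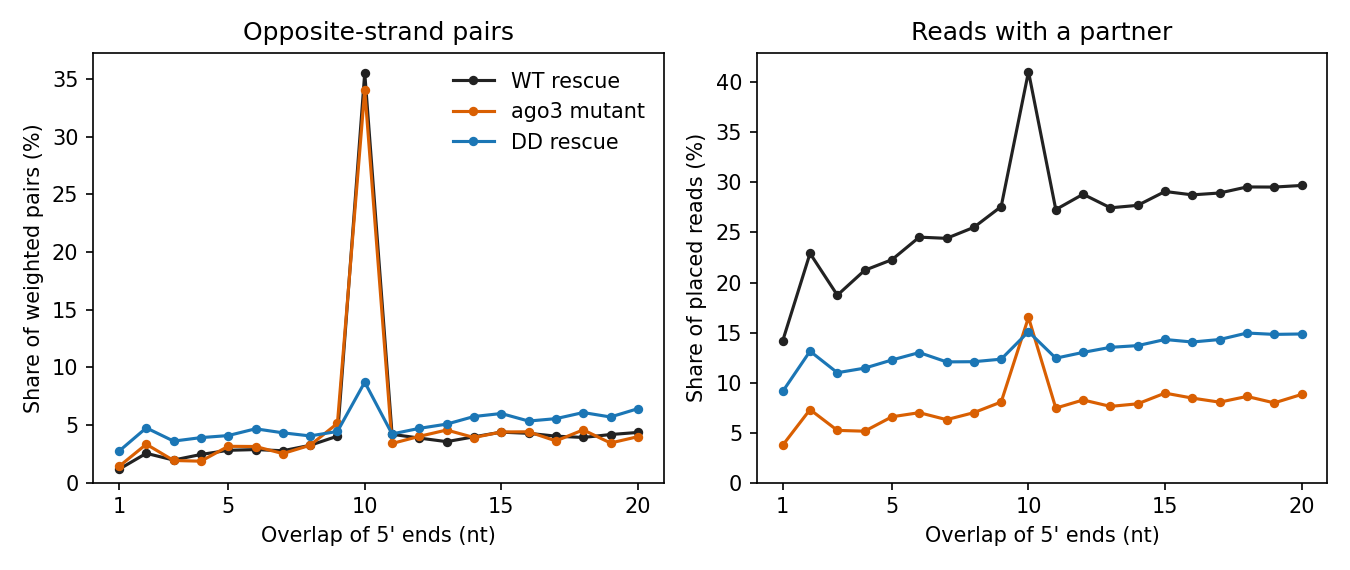
Overlap of opposite-strand 5′ ends from 1 to 20 nt against the share of count-weighted pairs (left) and the share of placed reads with a partner at that overlap (right), both in percent, 1 line per library. At 10 nt the pair share is 35.5% in WT rescue, 34.1% in the ago3 mutant and 8.71% in DD rescue, and the partnered share 41.1%, 16.5% and 15.1%.

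Among 106 dual-strand regions with at least 100 reads in every library after thinning, 10 nt was the most frequent overlap in 74 regions in WT rescue, 56 in the ago3 mutant and 29 in DD rescue. The median pair share over these regions was 23.8% (19.6 to 28.1), 16.8% (13.6 to 22.1) and 6.75% (6.03 to 7.41). Counting pairs of distinct sequences once at full depth, the pair shares were 6.90%, 9.87% and 5.81%. In dual-strand regions at 72989 placed reads each, they were 9.70%, 9.95% and 6.03%.

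The ago3 mutant was compared with WT rescue to see which piRNAs differ without a rescuing transgene. Dual-strand regions together held 121146 RPM in the ago3 mutant and 237353 in WT rescue. Of 594 such regions with enough reads, 385 were at least 2-fold lower, 1 was higher and 208 were neither, with a median log2 ratio of -1.40 (-1.53 to -1.29). The read minimum admits more regions through WT rescue, the deepest library. With the minimum asked of every library, the median was -0.72 and 37 of 137 regions were lower. With all libraries thinned to equal reads first, it was -1.15 and 164 of 298 were lower. The 97 uni-strand U-rich regions had a median of 0.01 (-0.99 to 0.32), with 38 at least 2-fold lower and 7 higher. The median was 0.65 over 31 regions with the minimum asked of every library. The split of lower and higher regions was 44 and 2 when scaled to microRNA reads, and 28 and 31 when scaled to the reduced piRNA total. The 36 uni-strand U-poor regions, which include rRNA, had a median of 0.81 (0.59 to 0.99).

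The 3 most abundant dual-strand regions of WT rescue differed by less than the median. Region 7, of 851 nt, was at -0.22 (-0.27 to -0.16), region 12 at -0.48 (-0.55 to -0.41) and region 16 at -0.66 (-0.74 to -0.59). The 10 regions with the lowest ratios each had 1 read in the ago3 mutant, fewer than the floor of 3 reads. They ran from region 433 at -7.47 (-12.77 to -4.98), with 434 reads in WT rescue, to regions 1185 and 1207 at -5.69 (-11.01 to -3.19). A further 15 regions had 0 reads in the ago3 mutant. The most abundant, region 775, had 236 reads in WT rescue and was at least 32.1-fold lower against the floor. The floor replaced 0 reads but not 1 read, so regions at 0 rank above comparable regions at 1 read. Which regions are truly lowest is therefore not known. The 10 highest included 0 dual-strand regions. Region 33, uni-strand and U-rich with the most abundant read TCACCCAAAATAGCAAACCCCATAACC, was highest at 3.33 (3.18 to 3.49). Region 13, which holds the 5′ end of 18S rRNA, was at 2.54 (2.44 to 2.63), and region 1, with another part of 18S rRNA, at 1.45 (1.40 to 1.51). Counting each distinct sequence once, relative to the distinct sequences of each library, gave a dual-strand median of -0.01. This covered the 261 regions that then had enough, with 60 at least 2-fold lower. The count was made at full depth, where WT rescue has more reads, and was not repeated at equal reads. Unequal depth may therefore affect it. Assembly from equal reads of each library gave a dual-strand median of -1.03. Scaling to microRNA reads moves every ratio of this comparison by -0.51, and scaling to the reduced piRNA total by 0.54. The dual-strand medians are then -1.91 and -0.86. Of the 594 dual-strand regions, 493 were at least 2-fold lower and 0 higher when scaled to microRNA reads. Scaled to the reduced piRNA total, 270 were lower and 5 higher. The reduced piRNA total takes regions 7 and 12 above 0.

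The DD transgene was compared with the WT transgene in the same background. Dual-strand regions held 93000 RPM in DD rescue. Of 596 such regions 467 were at least 2-fold lower in DD rescue than in WT rescue, 3 were higher and 126 neither, with a median log2 ratio of -2.01 (-2.09 to -1.89). With the minimum asked of every library, the median was -1.19 and 80 of 137 were lower; after thinning to equal reads it was -1.74 and 227, or 76.4%, were lower. The 100 uni-strand U-rich regions had a median of -0.74 (-1.23 to -0.46), with 43 at least 2-fold lower and 1 higher. Under the same settings this median was -0.14 and -1.61. The 39 uni-strand U-poor regions had a median of 1.03 (0.88 to 1.36).

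Region 7 was at -1.04 (-1.09 to -0.99), region 12 at -1.28 (-1.34 to -1.22) and region 16 at -2.01 (-2.09 to -1.93). Of the 10 lowest regions 7 were dual-strand. Region 1234 had 1 read in DD rescue and 119 in WT rescue, at -6.69 (-12.00 to -4.18), and region 360, with 9 and 458 reads, was at -5.46 (-6.60 to -4.52). Of the 10 highest 8 were uni-strand and U-poor. They included region 2 at 2.51 (2.46 to 2.56), region 13 at 2.42 (2.33 to 2.51) and region 1 at 2.01 (1.97 to 2.05). Region 4, which holds part of 28S rRNA, was at 1.35 (1.31 to 1.40). Counting each distinct sequence once, again at full depth only, gave a dual-strand median of -0.27 over 264 regions, with 74 at least 2-fold lower. Assembly from equal reads gave a dual-strand median of -1.58. Scaling to the reduced piRNA total moves every ratio here by 0.79, giving medians of -1.22 for dual-strand and 0.052 for uni-strand U-rich regions. Of the uni-strand U-rich regions 25 were then lower and 9 higher. Of the 596 dual-strand regions 339 were then at least 2-fold lower and 10 higher.

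**Figure D3:**
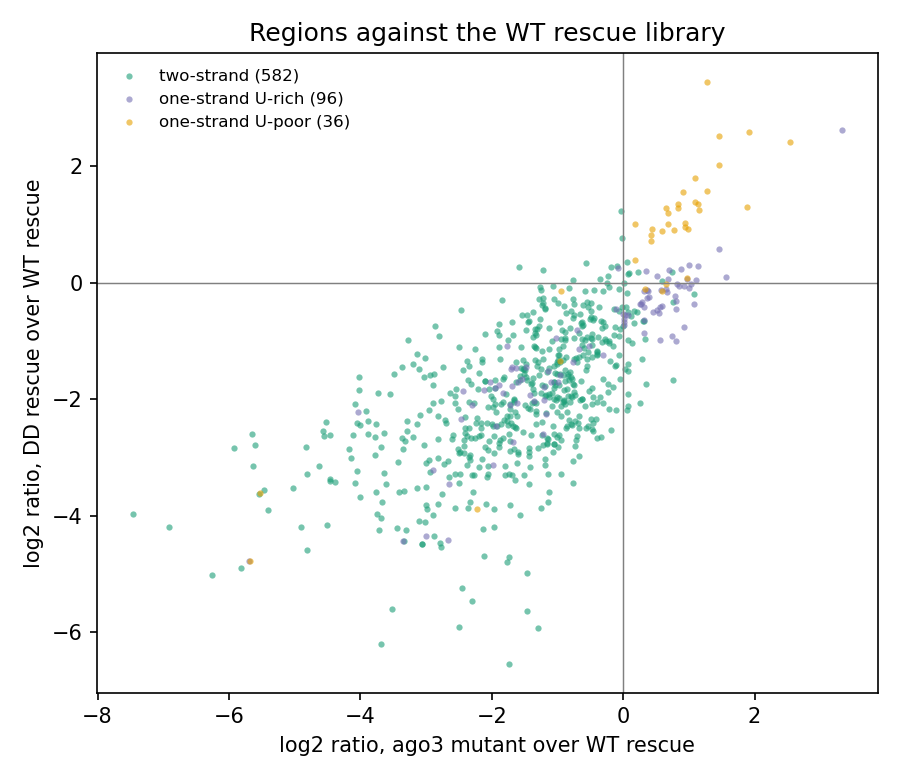
Log2 ratio of RPM of the ago3 mutant (horizontal) and of DD rescue (vertical) over WT rescue, 1 point per region with at least 100 reads in WT rescue and more than 0 in the other libraries. The 582 dual-strand regions (named two-strand in the plot) lie mostly below 0 on both axes, and the 36 uni-strand U-poor regions mostly above.

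DD rescue was also set against the ago3 mutant, to see on which side the DD transgene library stood. The 222 dual-strand regions had a median log2 ratio of -0.33 (-0.45 to -0.11), which reversed to 0.24 when scaled to microRNA reads. At least 2-fold lower in DD rescue were 51 of them, 20 were higher and 151 neither. With the minimum asked of every library the median was -0.56, and after thinning to equal reads -0.54. Scaled to microRNA reads 26 were lower and 49 higher, and scaled to the reduced piRNA total 42 and 32. Region 7 was at -0.82 (-0.89 to -0.76), region 12 at -0.80 (-0.88 to -0.72) and region 16 at -1.35 (-1.45 to -1.25). Of the 10 highest regions 9 were dual-strand, led by region 252 at 2.39 (1.63 to 3.26) and region 61 at 2.29 (1.98 to 2.61). The lowest was region 281 at -2.47 (-3.04 to -1.93), followed by the dual-strand region 377 at -2.42 (-2.93 to -1.93). Uni-strand U-rich regions had a median of -0.63 (-0.77 to -0.51) over 48 regions, with 5 at least 2-fold lower and 0 higher. It was -0.060 when scaled to microRNA reads, with 0 lower and 2 higher.

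Antisense reads accounted for most of the difference of the ago3 mutant from WT rescue in regions that could be oriented. An open reading frame on 1 strand oriented 32 of 46 long dual-strand regions. Their sense reads gave 25067 RPM in WT rescue, 24216 in the ago3 mutant and 16172 in DD rescue. Their antisense reads gave 34223, 14131 and 13038. On the log2 scale the ago3 mutant was at -0.05 (-0.08 to -0.02) for sense and -1.28 (-1.31 to -1.24) for antisense reads against WT rescue. DD rescue was at -0.63 (-0.66 to -0.61) for sense and -1.39 (-1.42 to -1.37) for antisense. These ratios are of summed reads, in which abundant regions weigh most. Medians over regions were -0.12 (-0.39 to 0.13) for sense and -1.16 (-1.72 to -0.94) for antisense in the ago3 mutant. In DD rescue they were -0.97 (-1.53 to -0.37) and -1.44 (-1.88 to -0.85). At least 2-fold lower in DD rescue were 16 of 32 regions for sense and 19 of 31 for antisense reads. The antisense ratio lay below the sense ratio in 28 of 32 regions in both comparisons, a contrast that no scaling factor can change. Between DD rescue and the ago3 mutant it lay below in 3 of 32 regions. Adenine at position 10 of sense reads was present in 49.96% in WT rescue, 46.2% in the ago3 mutant and 38.4% in DD rescue, and first-base U of antisense reads in 53.0%, 49.0% and 41.2%.

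**Figure D4:**
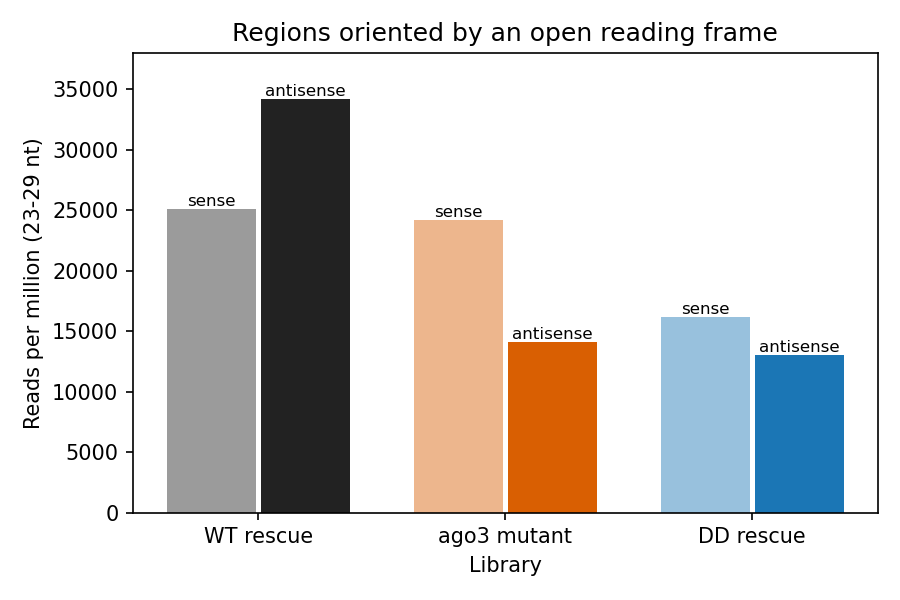
RPM of 23 to 29 nt from 32 dual-strand regions oriented by an open reading frame, as paired bars per library, sense light and antisense dark. Antisense reads exceed sense reads in WT rescue, 34223 against 25067, and lie below them in the ago3 mutant, 14131 against 24216, and in DD rescue, 13038 against 16172.

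The frames of 7 of these regions hold motifs found in reverse transcriptases or in endonucleases of retroelements. Region 18, with the motif YADD, gave 3932 RPM in WT rescue, 2536 in the ago3 mutant and 1880 in DD rescue. Region 20, with FADD, gave 3570, 1789 and 2796, and region 12, with SDHN, gave 5456, 3914 and 2246.

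How far both comparisons with WT rescue agree across regions, which are not replicates, depended on the regions chosen. Over 331 dual-strand regions with a mean of at least 100 reads, Pearson's r was 0.569 and Spearman's rho 0.544, against 0.366 and 0.342 in simulated unchanged libraries that share WT rescue. The covariance was 0.628 against 0.00751. At least 2-fold lower in the ago3 mutant were 173 regions, in DD rescue 234 and in both 148, where independent lists would share 122. Over the 137 regions with at least 100 reads in every library, r was 0.321 against 0.365 simulated and rho 0.293 against 0.343, while the covariance was 0.14 against 0.00332. Of these, 36 were lower in the ago3 mutant, 80 in DD rescue and 23 in both, where independent lists would share 21.02. Counting error of the shared library thus gave only a small covariance, 0.00751 and 0.00332, in the simulations. The simulated r and rho come from that counting error alone, so they do not measure how large the agreement is. Any other deviation of the WT rescue library enters both comparisons. Part of the agreement may come from it, and it could not be split off. The counts for independent lists leave this sharing out, and no overlap of lists was simulated under it.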

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

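Reads complementary to 2S rRNA were not part of any comparison. They gave 4222 RPM in the ago3 mutant and 5677 in DD rescue, above the 1741 in WT rescue, the library with the WT transgene. Reads of 2S rRNA itself gave 1592, 1023 and 352 in the same order. The labels state that 2S rRNA was depleted; the sequence of the oligonucleotide is not given in the sources used here. No explanation of these reads was tested.

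Of the tests below, those of depth and of structural RNA for reads with a 10-nt partner were written before their results were seen; all others, with the split by library, were chosen after. The share of reads with a 10-nt partner was 41.1% in WT rescue, 16.5% in the ago3 mutant and 15.1% in DD rescue; the tables argue against depth as the cause, since WT rescue thinned to the same reads stayed 2.04 times above the ago3 mutant and 2.98 times above DD rescue. Within dual-strand regions at equal placed reads the ratios of these shares shrank to 1.08 and 1.15. Both ratios met the outcome written beforehand for structural RNA as the cause. The excess at 10 nt over the other lengths was added as a measure after that. In WT rescue it was 1.09 times that of the ago3 mutant and 3.73 times that of DD rescue. For DD rescue this argues against structural RNA as the whole cause, since partners at other lengths make up most of its share there. For the ago3 mutant a larger part of structural RNA is a candidate explanation, which this test cannot separate from fewer dual-strand piRNAs. The genotype stays open as a biological explanation, and the parts disagree, so for both libraries at once the explanations cannot be told apart.

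First-base U was 46.1%, 38.9% and 28.7% in WT rescue, the ago3 mutant and DD rescue. The first test asked for both libraries at once whether distinct sequences without recognised RNAs come within 3 percentage points of WT rescue; WT rescue exceeded DD rescue by 5.93 and the ago3 mutant by 0.649, which met neither outcome. The libraries were then taken apart and reads of dual-strand regions added. For DD rescue the gap there was 8.19 points, so structural RNA is not the whole cause. For the ago3 mutant that gap was 4.50 points against 0.649 among distinct sequences, and the explanations cannot be told apart because these values disagree; the genotype stays untested.

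The pair share at 10 nt was 35.5% in WT rescue, 34.1% in the ago3 mutant and 8.71% in DD rescue. In dual-strand regions at equal placed reads the other libraries stayed at least 3.88 times above DD rescue, which argues against structural RNA and depth. Without the 100 most abundant sequences of each library they stayed at least 3.12 times above it and without the 1000 most abundant 1.81 times. The interval of the region median in the ago3 mutant began 1.84 times above the end of that in DD rescue. These values argue against a few abundant pairs as the whole cause, but the gap shrank. In dual-strand regions at equal placed reads the pair shares were 36.3%, 34.4% and 8.87% with all sequences, in the same order. They were 26.5%, 24.3% and 7.80% without the 100 most abundant, and 13.4%, 11.5% and 6.37% without the 1000. Whether the weight of abundant sequences in general is the cause cannot be told apart: distinct sequences counted once gave a ratio of at least 1.61 at equal placed reads and 1.19 at full depth. The genotype stays open and untested, and with 1 library per group a difference between library preparations or fly stocks cannot be excluded.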

How the results depend on the processing

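Of 225 values under other settings, for 34 results, 113 stayed within the interval of the main value or within 1.5 times a main count, 107 moved and 5 reversed. Of the 113, 13 could not differ, which leaves 100. The way of assembly lets no sequence have several places, and the ago3 mutant is itself the smallest library. Settings with 17-nt or 21-nt words, longer regions, equal assembly, recognised RNAs left out and the reduced piRNA total as scaling were added after seeing the data. So were the top pair region left out, shorter oriented regions and all scalings of the microRNA arms. The read minimum in every library and thinning before that minimum were also added then. Scaling of regions and oriented reads to microRNA or piRNA-length reads was fixed before. No paired analysis was possible because each group had 1 library. Normalization to flamenco, all settings of source loci and of transposon lists were not run, since no genome or transposon sequence was used here. Values are in the order WT rescue, ago3 mutant, DD rescue for shares, and ago3 mutant over WT rescue, DD rescue over WT rescue, DD rescue over ago3 mutant for ratios, unless named. The causes were not tested except where named. Interval widths of shares are narrow at this depth, so many moves are small; the smaller ago3 mutant library and its regions of 1 to 3 reads limit the lowest ratios.

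Counting each distinct sequence once gave 83.8%, 84.6% and 81.4% of 23 to 29 nt, first-base U of 44.6%, 43.9% and 38.6%, adenine at position 10 of 30.7%, 29.99% and 28.9%, and pair shares of 6.90%, 9.87% and 5.81%. Dual-strand medians were then -0.0097, -0.27 and 0.017, the last reversed, with 60 of 261, 74 of 264 and 2 of 114 regions at least 2-fold lower. These medians were taken at full depth only, so unequal depth may affect them. Uni-strand U-rich medians were 0.46 and -0.010 against WT rescue. At 24 to 27 nt, first-base U was 45.5%, 37.2% and 25.2%, adenine at position 10 33.2%, 26.6% and 20.2%, and the ago3 mutant over WT rescue had a dual-strand median of -1.27 and a uni-strand U-rich median of -0.58. Without the 100 most abundant sequences the shares were 46.2%, 41.0% and 32.9% for U and 34.5%, 31.5% and 28.1% for A. Without recognised RNAs they were 45.2%, 38.3% and 28.9% for U and 34.8%, 31.6% and 28.9% for A. The order of the 3 libraries in first-base U and in adenine at position 10 was the same in each of these settings.

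Normalized to microRNA reads, the dual-strand median was -1.91 for the ago3 mutant over WT rescue and reversed to 0.24 for DD rescue over the ago3 mutant, with 26 regions lower, and the uni-strand U-rich median of the latter was -0.060. Summed sense reads were at -0.56, -0.57 and -0.0087 and antisense reads at -1.78, -1.33 and 0.46, the last reversed. Normalized to piRNA-length reads, sense reads of the ago3 mutant over WT rescue reversed from -0.050 to 0.0037 and those of DD rescue over WT rescue were at -0.60, with antisense reads at -1.22 and -1.36. Normalized to the reduced piRNA total, which leaves out recognised RNAs and uni-strand U-poor regions, dual-strand medians were -0.86, -1.22 and -0.082, and uni-strand U-rich medians 0.55, 0.052 (reversed) and -0.38. These scalings shift all ratios of a comparison alike. The median of microRNA arms in the ago3 mutant over WT rescue was 0.037 normalized to microRNA reads, 0.60 to piRNA-length reads and 1.09 to the reduced piRNA total, with 0, 4 and 17 arms at least 2-fold higher and 1, 0 and 0 lower. For DD rescue over WT rescue it was 0.14, 0.11 and 0.86, with 1, 1 and 11 higher and 1, 1 and 0 lower.

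With at least 500 reads, fewer regions entered and the dual-strand medians against WT rescue were -0.98 and -1.46, with 72, 107 and 8 regions lower; the uni-strand U-rich medians against WT rescue were -0.97 and -1.58. With at least 20 reads more entered, with 630, 774 and 174 lower, and uni-strand U-rich medians against WT rescue of 0.53 and -0.25. With the read minimum asked of every library, dual-strand medians were -0.72, -1.19 and -0.56 over 137 regions, with 37, 80 and 36 lower, and uni-strand U-rich medians 0.65, -0.14 and -0.74 over 31. This choice leaves out regions with few reads in the ago3 mutant, and the main one lets in more through WT rescue. With all libraries thinned to equal reads before the minimum, dual-strand medians were -1.15, -1.74 and -0.54 with 164 (55.03%), 227 (76.4%) and 51 (31.3%) lower, and the uni-strand U-rich median of DD rescue over WT rescue was -1.61. Words of 21 nt gave dual-strand medians against WT rescue of -1.20 and -1.67, and words of 17 nt -2.14 for DD rescue. Regions of 100 nt or more gave -1.07 and -1.75 with 166 and 223 lower, and assembly from equal reads -1.03 and -1.58 with 223 and 311 lower. The uni-strand U-rich median of DD rescue over WT rescue was -0.41 and -0.45 in these. Oriented regions of 150 nt or more gave sense ratios of -0.24, -0.72 and -0.48 and antisense ratios of -1.36 for the ago3 mutant over WT rescue and -0.028 for DD rescue over the ago3 mutant. Pearson's r of both comparisons with WT rescue was 0.321 in place of 0.569 when the read minimum was asked of every library. In every setting run with all libraries, dual-strand medians against WT rescue were below 0, and the pair share at 10 nt was lowest in DD rescue. With distinct sequences counted once, however, the median of the ago3 mutant was -0.0097 (-0.18 to 0.074), an interval that includes 0.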

Other observations

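Phasing and siRNA duplexes were looked at as well. The distance from a 3′ end to the next 5′ end on the same strand, whose value at adjacent positions marks phased piRNAs, had z-scores of 1.93 in WT rescue, 1.71 in the ago3 mutant and 2.85 in DD rescue. Adjacent positions held 7.55%, 7.32% and 6.23% of pairs, against 8.50%, 7.76% and 6.17% at the highest other distance, so only in DD rescue did they hold the most. Among 21-nt reads without recognised RNAs, all libraries thinned to equal reads, 1.66%, 1.05% and 1.11% had a partner at the 19-nt overlap of siRNA duplexes, each below the mean of the other overlaps at 1.73%, 1.47% and 1.33%. At full depth the values were 2.77%, 1.05% and 1.79%, against 3.22%, 1.47% and 2.34%.

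Sequences shared between the pools of 23 to 29 nt reads without recognised RNAs held a larger part of reads than of distinct sequences. These pools are not piRNAs alone. Before thinning, uni-strand U-poor regions, which include rRNA, held 6.93% of them in WT rescue, 17.7% in the ago3 mutant and 24.8% in DD rescue. At 330224 reads per library, 27786 distinct sequences were shared by the 190856 of WT rescue and the 121608 of the ago3 mutant, and 31606 by WT rescue and the 155836 of DD rescue. The ago3 mutant and DD rescue shared 27269. By reads, 33.4% of WT rescue reads had a sequence found in the ago3 mutant and 35.4% one found in DD rescue. Of the ago3 mutant reads, 47.5% had a sequence found in WT rescue and 47.97% one found in DD rescue. Of the DD rescue reads, 51.4% had a sequence found in WT rescue and 51.03% one found in the ago3 mutant.

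A measure that needs no assembly was computed as well. Count-weighted complementarity of the first 10 bases of reads exceeded that of shuffled sequences 17.1-fold in WT rescue, 9.33-fold in the ago3 mutant and 2.72-fold in DD rescue.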
